A study of Mus musculus with 3 samples.

How the data were processed

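Total RNA of 3 samples of mouse CD4 T cells was measured, each on 1 single-colour Affymetrix array. Per the labels, the samples were Th0, Th22 and Th17 cells, taken after 60 hours of culture, and each sample was grouped by the T-helper subset its labels give. The deposited table held 28853 probes on what was assumed to be a log2 scale, as differences from each probe's own median over the 3 arrays. That centring was found from the values: the median over the arrays was exactly 0 for all 28853 probes. The median of each of the 3 columns was also 0. The probe summary, background correction, normalization, software and log base are not given in the sources used here. Base 2 was assumed. Of 27445 non-zero values 97.7% lay within 0.05 of a whole multiple of 1 over 2 to the power 21, the step left by single-precision log values of at least 4, but this does not identify the base. Every fold given rests on the assumption, and with natural logs each fold would be larger. The direction is not stated either, and a higher value was taken as higher expression.

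The centring removed expression levels, so signal over background is unknown, and a gene equal on all arrays cannot be told from one that was not detected. Of the probes, 11627 (40.3%) were exactly equal on all 3 arrays and 7007 (24.3%) on 2 of them. Differences between arrays are not altered by the centring. The plan made before the data were examined had a floor on the level, the brightest probe of each gene and random lists matched on mean expression, none of which can be had from centred values. All probes were kept instead, the probes of a gene were averaged, and random lists were matched on the number of members equal on all 3 arrays. These replacements were chosen after seeing the data.

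Probes were named from the platform annotation, and symbols were updated by Entrez identifier with a gene table of assembly GRCm38.p6, used for names alone, which matched 21698 of 21789 probes with 1 symbol. Another 1621 probes had several symbols and 5443 were not listed, and both kinds were left out of gene counts. This gave 19938 genes, 999 of them with more than 1 probe. No genome build is named in the sources used here, and no coordinates are given.

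With 1 array per group no test was run. A gene was counted where arrays differed by at least 2-fold. The only repeat measurement was between separate probes of 1 gene. Over 999 genes the difference between such probes had an SD of 0.18 log2 for Th17 against Th22, 0.14 for Th22 against Th0 and 0.19 for Th17 against Th0, and 95% of genes lay within 0.36, 0.30 and 0.39. Where at least 1 of the probes differed between the arrays the SD was 0.21, 0.16 and 0.22. Among genes past 2-fold by the mean of such probes, the probes lay over 1 log2 apart in 3 of 13, 0 of 5 and 3 of 21. This covers probe error and leaves out the spread between cultures. The count was tested on simulated data with the error of all 999 genes, which may understate that of genes past 2-fold. Of 67 genes planted at 1.5 log2, 66 were found in each comparison, as were all 66 planted at 3 log2. Of 67 planted at 0.75 log2, 2 were found for Th17 against Th22, 1 for Th22 against Th0 and 1 for Th17 against Th0. Of 19738 unchanged genes 27, 0 and 57 passed, in the same order.

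The 28 gene lists were fixed before the data were examined. They were the Th17, Th1, Th2, Treg and Tfh programs, the aryl hydrocarbon receptor pathway, the TGFβ, IL-6 and STAT3, and interferon responses, cytotoxic effector genes, cytokines, lineage transcription factors, chemokine receptors and homing, activation and costimulation, coinhibitory receptors, naive T cell genes, cell cycle, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, class II antigen presentation, pan T cell genes, and markers of B cells, myeloid and dendritic cells, CD8 and NK cells, gamma-delta T cells, and erythroid cells and platelets. Some genes are on several lists. Il22 is on those of the Th17 program, the aryl hydrocarbon receptor pathway and cytokines. The pair of probes that matches it also matches Iltifb and was left out of them. Each list's median difference was placed among 10000 random lists of the same size, and those below percentile 1 or above percentile 99 were said to stand apart, for the 27 lists with at least 5 measured members. Many genes are exactly 0, so a small median can stand apart. The percentile describes these arrays and is not a test of the conditions. Of 500 simulated unchanged lists 1%, 1.8% and 2% stood apart in Th17 against Th22, Th22 against Th0 and Th17 against Th0. The cut-offs fix this share in advance, because these lists and their random lists were drawn, unmatched, from the same simulated values. It therefore says nothing about lists whose members vary together. The named genes are the members of the lists, the 15 largest differences in each direction for Th17 against Th22 and the 12 largest in each direction for each comparison with Th0, leaving out gene models, small RNAs, receptor segments and sensory receptors. Probes of 1 gene were said to disagree where they lay over 1 log2 apart.

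Alternatives were quantile normalization of the columns, median centring, thresholds of 1.5-fold and 3-fold, and random lists without matching. The lowest probe ID per gene, every probe as its own entry, and every probe with alike probes counted once were added after seeing the data. The overlap of both comparisons with Th0 was set beside simulated unchanged arrays that share 1 control. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.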

Results

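Gene expression was measured on microarrays in mouse CD4 T cells grown under 3 conditions, to look for what separates the Th22 and Th17 programs. The T cells came from spleens of OT-II mice, whose transgenic receptor recognises an ovalbumin peptide. Cells sorted as naive were activated with that peptide on antigen-presenting cells from mice lacking Il23a. Th22 cells received IL-6, Th17 cells received IL-6 with TGFβ, and Th0 cells received no added cytokine. After 60 hours the cells were purified with magnetic beads and their RNA was hybridised to a biotin-labelled, single-colour array. Each condition had 1 array, so no difference given here has a replicate check, and the number of arrays limits the precision. Differences are given for 19938 genes, as folds that assume log base 2.

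The comparison of Th17 with Th22 asks what differs between cells given TGFβ with IL-6 and cells given IL-6 alone. In Th17, 220 genes were at least 2-fold higher and 300 at least 2-fold lower than in Th22. Among the named genes the largest difference was in Gzmb, which encodes the cytotoxic protease granzyme B and was 89.3-fold lower in Th17. Gja5, a gap junction gene, was 28.8-fold higher in Th17, and Nt5e, which encodes the ectoenzyme CD73, was 24.3-fold higher. Aqp3, a water and glycerol channel gene, was 21.4-fold higher, and the anti-inflammatory cytokine gene Il10 was 21.1-fold higher. Ccl20, which encodes the ligand of CCR6, was 18.6-fold higher, Il9 14.9-fold and Foxp3, the regulatory T cell transcription factor gene, 12.6-fold. The kinase gene Sgk1 (11.5-fold), the transcription factor gene Maf (11.4-fold), Nipal1 (11.2-fold), Pdpn (11.2-fold), Cd101 (9.79-fold), Ldlrad4 (9.77-fold), Gcnt2 (9.52-fold) and Procr (8.79-fold) completed the 15 largest differences towards Th17.

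After Gzmb, the genes lowest in Th17 relative to Th22 were the interferon-induced Ifitm3 (29.9-fold lower), the cytokine gene Il3 (29.3-fold), Akr1c18 (25.6-fold) and Tnfsf8, which encodes CD30 ligand (21.5-fold). The cytotoxic granule gene Nkg7 was 20.8-fold lower, Serpinb6b 20.4-fold, Lum 17.6-fold, Nrn1 17.4-fold, Tnip3 14.4-fold and the enkephalin precursor gene Penk 14.0-fold. Serpinb9, which encodes an inhibitor of granzyme B, was 11.8-fold lower, Lilr4b 11.2-fold, Lilrb4a 10.2-fold and Pglyrp1 10.2-fold. Lilr4b and Lilrb4a, and the Serpinb, Gzm and Ifitm families, include close relatives, so the assignment of their signal to single members is uncertain.

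The Th17 program was mostly higher in Th17 than in Th22. Of 17 measured members 10 were at least 2-fold higher, 2 at least 2-fold lower and 5 within 2-fold, with a median difference of 1.32 log2, above the 99th percentile of random lists. Besides Ccl20 and Il9, the chemokine receptor gene Cxcr6 was 4.33-fold higher, Il17a 3.96-fold, the nuclear receptor gene Rora 3.03-fold and Il17f 2.62-fold. Il23r, which encodes a chain of the IL-23 receptor, was 7.33-fold lower in Th17 and Plxnd1 2.42-fold lower. Iltifb, a near-identical copy of Il22, was 3.32 log2 lower in Th17. A pair of probes that match both Iltifb and Il22 was 8.40-fold and 8.21-fold lower, and the signal cannot be assigned to one copy. Of 7 genes of the aryl hydrocarbon receptor pathway only Ahr, the receptor gene, passed 2-fold (3.61-fold higher in Th17), and the median was 0. Il22 is on that list and on the Th17 list, but the pair of probes shared with Iltifb was counted in neither.

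The regulatory T cell and TGFβ-response lists had positive medians for Th17 against Th22, with only part of their members past 2-fold. In the Treg list 9 of 19 members were at least 2-fold higher, 1 was lower and 9 were within 2-fold, with a median of 0.83 log2. Beside Nt5e, Il10 and Foxp3, the homing receptor gene Gpr15 was 6.09-fold higher, Entpd1, which encodes CD39, 3.76-fold, and Itgae, which encodes CD103, 2.59-fold. Tnfrsf18 was 2.11-fold lower. In the TGFβ list 8 of 23 members were higher, 2 lower and 13 within 2-fold, with a median of 0.46 log2. The receptor gene Tgfbr1 was 6.61-fold higher, Pmepa1 4.33-fold, Skil 3.70-fold and the inhibitory Smad gene Smad7 2.30-fold, while Id3 was 3.35-fold and Tgfb3 2.12-fold lower. Both medians lay above the 99th percentile of random lists.

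The Th1, Th2, cytotoxic and interferon-response lists had negative medians for Th17 against Th22, although most of their members lay within 2-fold. In the Th1 list 8 of 18 members were at least 2-fold lower, 0 higher and 10 within 2-fold, with a median of -0.67 log2. Tbx21, which encodes the Th1 factor T-bet, was 6.30-fold lower, Il12rb2 5.88-fold and Cxcr3 4.18-fold, and Ifng was 1.58-fold lower, inside the threshold. In the Th2 list 3 of 13 members were lower, namely Il3, the Th2 factor gene Gata3 (6.27-fold) and Il13 (2.13-fold), and 1 was higher, Ccr8 (4.79-fold), and 9 within 2-fold, with a median of -0.30 log2. Of 21 cytotoxic effector genes 7 were lower, including Gzma (4.85-fold) and the perforin gene Prf1 (2.20-fold), and 2 were higher, Klrd1 (7.55-fold) and Ctsw (3.95-fold), and 12 within 2-fold, with a median of -0.25 log2. Of 29 interferon-response genes 5 were lower, 0 higher and 24 within 2-fold, with a median of -0.40 log2. Among them the RNA sensor gene Ifih1 was 2.81 log2 lower, Gbp4 3.85-fold and Oas3 3.47-fold. All 4 medians lay below the 1st percentile of random lists. Beside these groups, 2 of 10 CD8 and NK cell markers, Gzma and Cd8b1 (2.20-fold), and 1 of 8 class II presentation genes, the invariant chain gene Cd74 (2.28-fold), were lower in Th17. The class II median was -0.18 log2, below the 1st percentile of random lists.

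**Figure D1:**
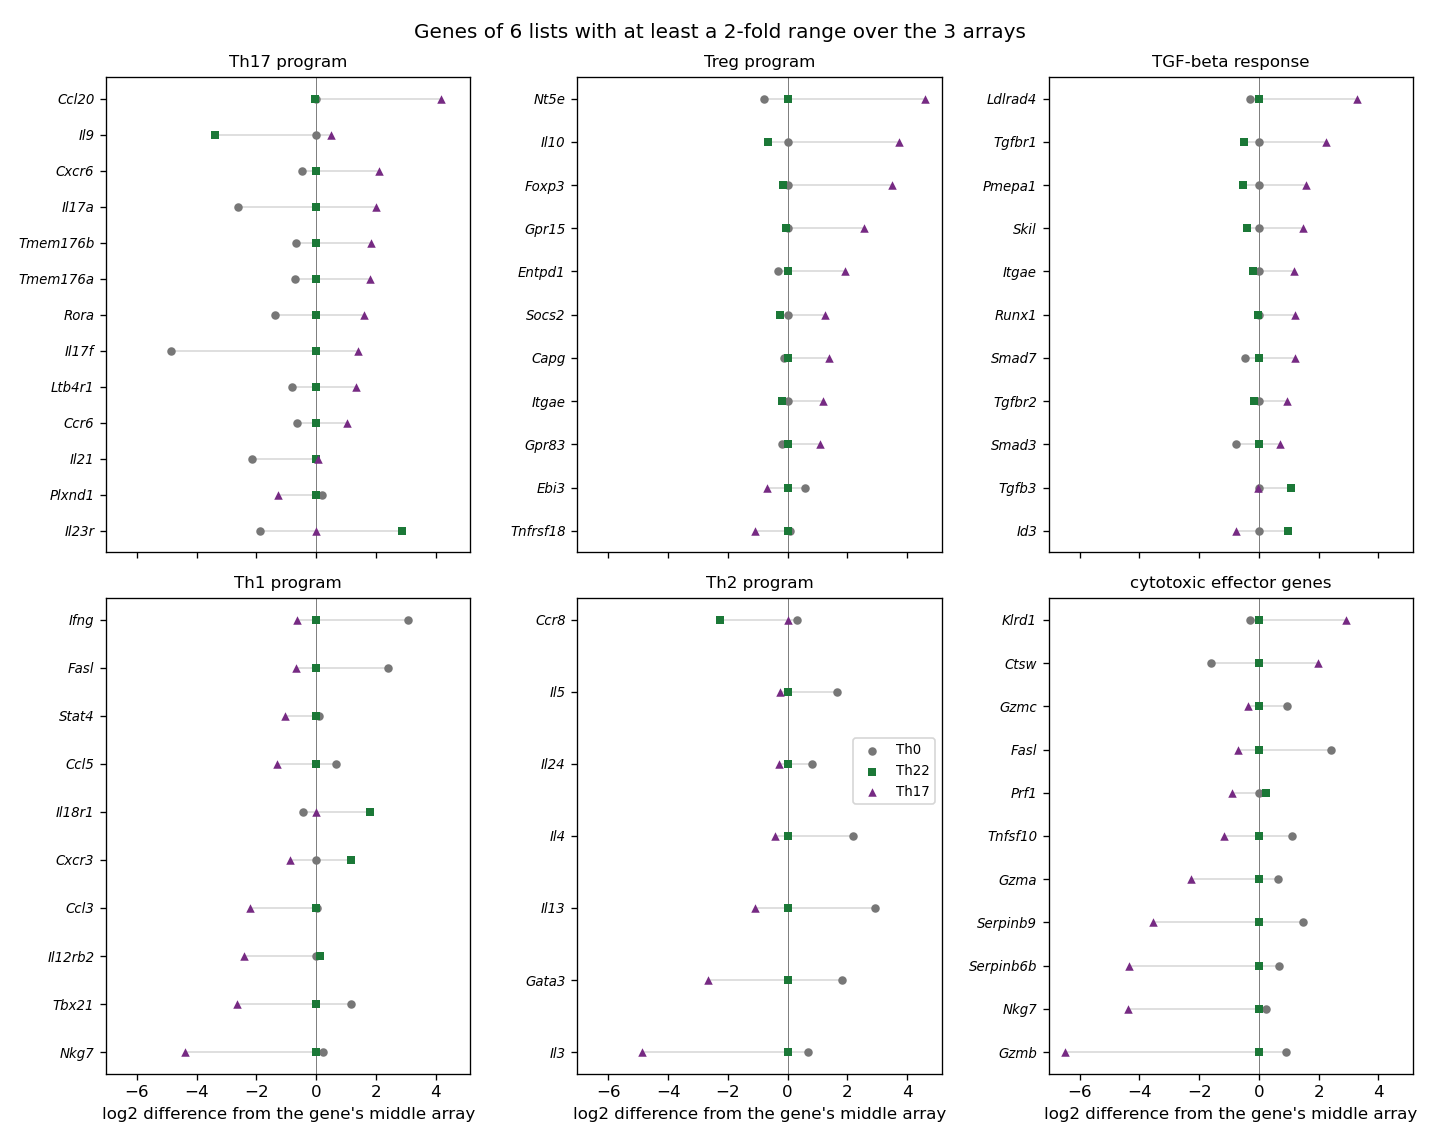
Genes of 6 lists whose highest and lowest arrays lie at least 2-fold apart, with the log2 difference from each gene's middle array on the horizontal axis; circles are Th0, squares Th22 and triangles Th17, with 1 array each and no error bars. In the Th17 panel Il23r is highest in Th22, and in the cytotoxic panel Gzmb lies lowest in Th17.

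Lineage transcription factor genes differed both ways between Th17 and Th22. Of 35 measured, 7 were at least 2-fold higher in Th17 (Foxp3, Maf, Ahr, Ikzf3, Rora, Runx1 and Bcl6) and 4 lower (Tbx21, Gata3, Id3 and Stat4), with a median of 0. Of 21 genes of the IL-6 and STAT3 response 4 were higher, Il10, Maf, the receptor chain gene Il6st (3.62-fold) and Bcl6 (2.04-fold), and 0 lower, with a median of 0.05 log2. Of 15 Tfh genes 4 were higher, including Pou2af1 (5.58-fold) and Cxcr5 (4.54-fold), and 4 lower, including Btla (4.37-fold) and Cd200 (3.22-fold), with a median of 0.05 log2. None of 26 myeloid and dendritic cell markers differed by 2-fold, 17 of them being equal on all 3 arrays. Of 14 B cell markers Cd72 was 2.53-fold higher and Ebf1 6.36-fold lower in Th17. All 11 pan T cell genes lay within 2-fold, but 9 of them were lower in Th17 by some amount, with a median of -0.24 log2, below the 1st percentile of random lists. Forcing equal spread on the arrays by quantile normalization kept 316 of the 520 genes, with 0 turned. Of the 103 differences of at least 2-fold in named genes it left 26 under 2-fold, including those of Il17f, Il13, Prf1, Cd74, Cd8b1, Cd72, Smad7, Bcl6, Runx1, Stat4, Plxnd1 and Tnfrsf18.

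Th22 was compared with Th0 to describe cells given IL-6 alone. In Th22, 109 genes were at least 2-fold higher and 52 at least 2-fold lower than in Th0, against 150 and 158 after quantile normalization. That procedure forces equal spread on the arrays and so can itself raise these counts. The Th17 cytokine gene Il17f was 29.0-fold higher in Th22, Il23r 26.8-fold, Timp1, which encodes an inhibitor of matrix proteases, 23.4-fold and Ly6g 19.5-fold. Iltifb was 18.0-fold higher, and the pair of probes matching Iltifb and Il22 28.8-fold and 28.7-fold higher. Serpinb5 was 17.4-fold higher, Lum 13.5-fold, Serpinb1a 12.8-fold, Il17a 6.14-fold, Crispld2 2.59 log2, Cdh17 5.61-fold and the IL-1 decoy receptor gene Il1r2 5.56-fold. Dapl1 was 20.7-fold lower in Th22 than in Th0, Il9 10.5-fold, Ifng 8.36-fold, Il13 7.68-fold and the interferon-inducible GTPase gene Iigp1 6.64-fold. Ccr8 (6.03-fold), Epas1 (5.92-fold), Csf2 (5.86-fold), Cd83 (5.76-fold), Fasl (5.27-fold), Pros1 (4.65-fold) and Il4 (4.60-fold) were also among the 12 lowest.

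In the Th17 list 5 of 17 members were at least 2-fold higher in Th22 than in Th0, namely Il17f, Il23r, Il17a, Il21 (4.46-fold) and Rora (2.62-fold). Il9 was lower, and the median was 0.72 log2, above the 99th percentile of random lists. In the Th2 list 5 of 13 were lower, Gata3 by 3.50-fold and Il5 by 3.14-fold in addition to Il13, Ccr8 and Il4, and 0 were higher, with a median of -0.68 log2, below the 1st percentile. Of 18 Th1 genes Ifng, Fasl and Tbx21 (2.27-fold) were lower while Il18r1 (4.68-fold) and Cxcr3 (2.26-fold) were higher, with a median of -0.05 log2. Of 21 cytotoxic genes Fasl, Serpinb9 (2.76-fold) and Tnfsf10 (2.15-fold) were lower and Ctsw (3.07-fold) higher, with a median of -0.07 log2, and Gzmb was 1.88-fold lower. Of 29 interferon-response genes 3 were lower, Iigp1, Usp18 (2.56-fold) and Irgm1 (2.54-fold), with a median of -0.12 log2. The cytotoxic and interferon medians lay below the 1st percentile of random lists. Of 23 TGFβ-response genes only Tgfb3 passed 2-fold (2.08-fold higher), with a list median of 0.04 log2. None of 19 Treg genes did, and that list's median (0.03 log2) and mean (-0.0043 log2) had opposite signs.

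Among 21 IL-6 and STAT3 genes Il21 and Tnfrsf8 (2.06-fold) were higher in Th22 than in Th0, with a median of 0.08 log2. Of 15 Tfh genes Il21 and Cxcr5 (2.43-fold) were higher, with a median of 0.33 log2. Both medians lay above the 99th percentile of random lists. None of 7 counted aryl hydrocarbon receptor pathway genes differed by 2-fold (median 0.0059 log2). The pair of probes matching Il22, a member of that list, also matches Iltifb and was left out of the count. These probes were 28.8-fold and 28.7-fold higher in Th22, so the median does not speak for Il22. Of 35 lineage factors Rora was higher and Gata3, Tbx21 and Irf8 (2.04-fold) were lower, with a median of 0.09 log2, above the 99th percentile. Among markers of other cells, Ebf1 was 3.07-fold and Klrc1 2.11-fold higher in Th22, and none of 26 myeloid and dendritic or 8 class II genes (class II median -0.02 log2) differed by 2-fold. The 11 pan T cell genes lay within 2-fold, but 11 of them were higher in Th22 by some amount, with a median of 0.11 log2.

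Th17 was compared with Th0 to describe cells given both cytokines. In Th17, 293 genes were at least 2-fold higher and 311 at least 2-fold lower than in Th0. Il17f was 76.0-fold higher, Nt5e 41.6-fold, Timp1 36.0-fold, Serpinb1a 34.4-fold, Aqp3 27.9-fold, Gja5 26.8-fold and Il17a 24.3-fold. Emp1 (21.3-fold), Maf (18.7-fold), Ccl20 (18.3-fold), Gcnt2 (16.5-fold) and Nipal1, which lay just below Gcnt2, followed. Gzmb was 168-fold lower in Th17 than in Th0, Dapl1 65.7-fold, Penk 55.0-fold, Il3 47.1-fold and Akr1c18 38.1-fold. Tnfsf8 (32.9-fold), Serpinb6b (32.6-fold), Serpinb9 (32.6-fold), Nkg7 (24.4-fold), Gata3 (22.0-fold), Plxnc1 (17.2-fold) and Ifitm3 (16.9-fold) completed the 12 lowest.

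In the Th17 list 11 of 17 members were at least 2-fold higher in Th17 than in Th0, among them Rora (7.94-fold), Il21 (4.61-fold) and Il23r (3.66-fold), and Plxnd1 was 2.75-fold lower, with a median of 2.12 log2. In the Treg list 9 of 19 were higher, including Il10 (13.2-fold) and Foxp3 (11.3-fold), and Ebi3 (2.41-fold) and Tnfrsf18 (2.25-fold) were lower, with a median of 0.58 log2. In the TGFβ list 8 of 23 were higher, including Ldlrad4 (12.1-fold) and Smad7 (3.20-fold), and 0 lower, with a median of 0.77 log2. Of 21 IL-6 and STAT3 genes 8 were higher, including Socs3, a feedback inhibitor of IL-6 signalling (2.13-fold), and Prdm1 was 2.18-fold lower, with a median of 0.27 log2. Of 15 Tfh genes 6 were higher, including Cxcr5 (3.46 log2) and Bcl6 (4.04-fold), and 2 lower, Btla (3.47-fold) and Cd200 (3.09-fold), with a median of 0.39 log2. Ahr was 4.23-fold higher, the only counted member of its pathway past 2-fold, and that list's median was 0.49 log2, with the probes matching Il22 left out. Of 35 lineage factors 7 were higher and 4 lower, with a median of 0.05 log2. All 7 medians lay above the 99th percentile of random lists.

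Th1 genes had 8 of 18 members at least 2-fold lower in Th17 than in Th0 and 0 higher, with Tbx21 at 14.3-fold, Ifng at 13.2-fold and a median of -0.84 log2. Th2 genes had 6 of 13 lower and 0 higher, with Il13 at 16.3-fold, Il4 at 6.13-fold and a median of -0.85 log2. Of 21 cytotoxic genes 8 were lower, including Gzma (2.91 log2), and Ctsw (12.1-fold) and Klrd1 (9.32-fold) were higher, with a median of -0.25 log2. Of 29 interferon-response genes 10 were lower and 0 higher, led by Iigp1 (9.79-fold), Ifih1 (7.64-fold), Gbp4 (7.63-fold) and Usp18 (6.27-fold), with a median of -0.72 log2. Irf1 was among them (2.22-fold), but its probes disagreed by 1.63 log2. The 4 medians lay below the 1st percentile of random lists. Beside these groups, Cd74 was 3.93-fold lower, the only one of 8 class II genes past 2-fold, although 6 were lower by some amount (median -0.26 log2, below the 1st percentile), and Cd8b1 (2.61-fold) and Ebf1 (2.08-fold) were lower and Cd72 (2.62-fold) higher. None of 26 myeloid and dendritic markers and none of 11 pan T cell genes (median -0.04 log2) differed by 2-fold. Quantile normalization kept 403 of the 604 genes, with 0 turned, and left 18 of 121 differences of named genes under 2-fold, including those of Ebf1, Cd72, Cd8b1, Cd200, Plxnd1 and Tnfrsf18.

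**Figure D2:**
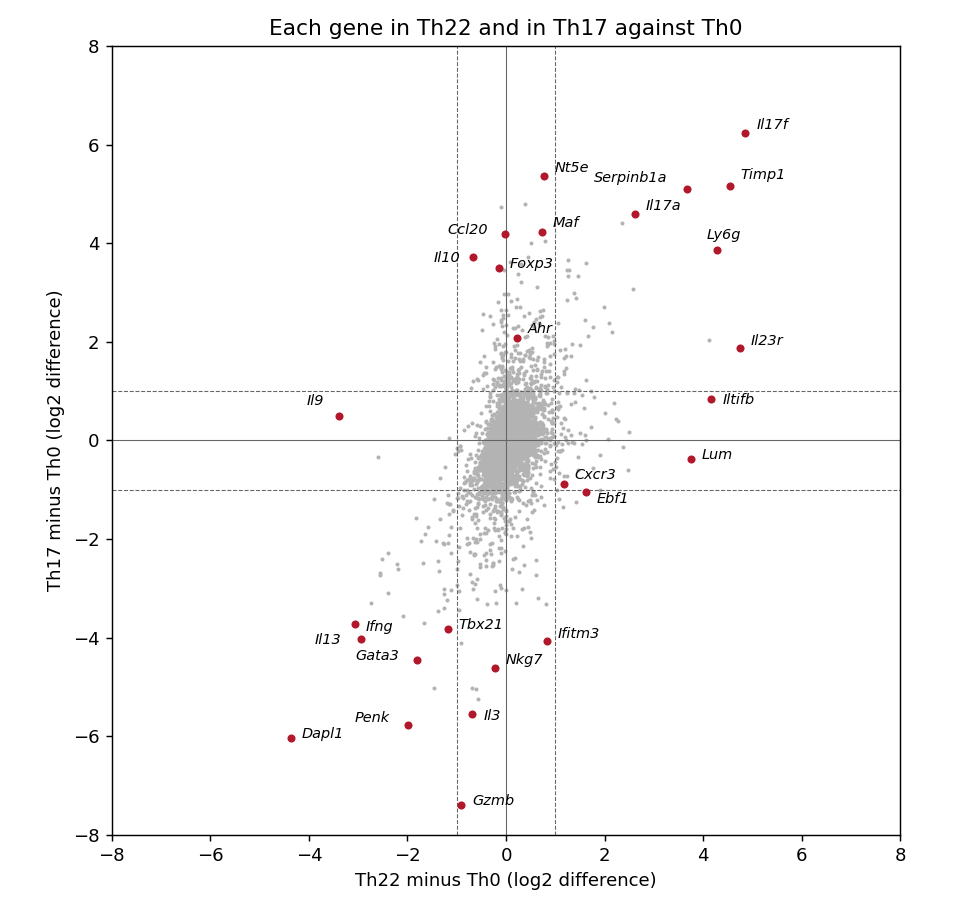
Each point is 1 of 19938 genes, with the log2 difference between Th22 and Th0 on the horizontal axis and between Th17 and Th0 on the vertical axis, 1 array per condition; dashed lines mark 2-fold, and the 27 red points are a selection of the named genes. Il17f lies high on both axes, Foxp3 and Ccl20 are high on the Th17 axis alone, and Lum is high on the Th22 axis alone.

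The differences of Th22 and of Th17 from Th0 were set against each other to describe what the cells given IL-6 had in common. Il17f, Il17a, Il21, Il23r, Rora, Timp1, Serpinb1a and Ly6g were at least 2-fold higher than in Th0 in both, and Ifng, Il13, Il4, Il5, Gata3, Tbx21, Dapl1 and Penk were at least 2-fold lower in both. The pair of probes matching Iltifb and Il22, highest in Th22, was also higher in Th17 than in Th0, by 3.43-fold and 3.49-fold. In all 43 genes were higher in both, 39.4% of the 109 higher in Th22, and 46 were lower in both, 88.5% of the 52 lower in Th22. After quantile normalization, which forces equal spread and so can itself move these counts, they were 42 genes, 28% of 150, and 82 genes, 51.9% of 158. Independent lists of these sizes would share 1.60 and 0.81 genes, a value that leaves out the shared Th0 array. Simulated unchanged arrays shared 0 and 0, but they carry probe error alone, which left no gene past 2-fold for Th22 against Th0, so this bounds nothing. Across genes, which are not independent replicates, the correlation of both differences was 0.49 (Spearman 0.40), against 0.50 in simulated unchanged arrays with a shared control. The simulated value is fixed by the shared control whatever the size of the error. Its likeness to the measured one thus does not show that nothing else is shared. The covariance of both differences was 0.0459 against a simulated 0.00488, which again leaves out the spread between cultures. How much of the overlap comes from the single Th0 array, which cannot be split, is not known. Of the 220 genes higher in Th17 than in Th22, 201 were 2-fold higher in Th17 than in Th0 and 203 lay within 2-fold of Th0 in Th22. Of the 300 genes lower in Th17 than in Th22, 206 were 2-fold lower in Th17 than in Th0, and in Th22 235 lay within 2-fold of Th0, 48 were 2-fold higher and 17 were 2-fold lower.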

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

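No tests were run on these results, which were picked out after the values were seen. Ebf1, a transcription factor gene of the B cell lineage, was the only named gene at least 2-fold from Th0 in opposite directions, by 1.62 log2 in Th22 and by -1.05 log2 in Th17. This difference was not tested, and its Th17 part was under 2-fold after quantile normalization. In all, 6 genes did so, the others being Dhx58, Ermn, Kdelr3, Tgm1 and Upp1, which are named because of their values. Outside the gene counts, a pair of probes that match both Iltifb and Il22 lay 4.85 and 4.84 log2 higher in Th22 than in Th0. Probes that the annotation does not list differed by at least 2-fold 35 times for Th17 against Th22, 66 times for Th22 against Th0 and 89 times for Th17 against Th0. Of the 62 such probes higher in Th22 than in Th0, 50 lay within 0.005 log2 of one pattern on all 3 arrays, with medians 1.10 log2 above Th0 in Th22 and 1.02 in Th17, and 12 others did not.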

How the results depend on the processing

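Chosen after seeing the data were, in the main setting, keeping all probes, averaging the probes of a gene and matching random lists on tied members, and, among the alternatives, the lowest probe ID per gene, every probe as its own entry, and every probe with alike probes counted once. Quantile normalization, which by construction gives the arrays equal spread, gave 158 genes lower in Th22 than in Th0 and 82 lower in both Th22 and Th17. The Th22 column had the narrowest range (-3.40 to 3.76, against -4.86 to 4.37 for Th0 and -6.48 to 4.75 for Th17). Equal spread stretches a narrow column and shrinks a wide one, so these shifts follow at least in part from the procedure. Quantile normalization changed the share of higher genes from 67.7% to 48.7% for Th22 against Th0 and from 48.3% to 33.9% for the genes shared by both. It kept 316 of 520 genes for Th17 against Th22, 161 of 161 for Th22 against Th0 and 403 of 604 for Th17 against Th0, with 0 turned in any of them, and no list median changed sign. It was run on columns of differences and raised the genes for Th22 against Th0 to 308, so keeping 161 of 161 does not measure stability. It moved 433 of 1374 differences of named genes by more than the spread between probes of 1 gene, which is no yardstick for list medians, so how far those moved was not judged. A threshold of 1.5-fold, wider by construction, gave 422 genes higher and 671 lower for Th17 against Th22, 319 and 161 for Th22 against Th0, 595 and 665 for Th17 against Th0, and 151 and 135 in both. A threshold of 3-fold gave 105 and 139, 37 and 22, 146 and 144, and 16 and 19, in the same order. Every probe as its own entry gave 179 higher in Th22 than in Th0 and 102 higher in both, and 128 and 53 once probes alike at 2 decimals were counted once. With the lowest probe ID all 8 counts stayed within 1.5 times, and 10 of 1374 differences of named genes moved. Only 999 of 19938 genes have more than 1 probe and could change at all, so this says little about stability. Lists standing apart numbered 13, 13 and 19 of the 27 lists with at least 5 measured members for Th17 against Th22, Th22 against Th0 and Th17 against Th0, and 17, 19 and 20 with random lists that were not matched. Median centring moved nothing because each column's median is 0, so it says nothing about stability. Cyclic loess, the filters on dim probes and the added offset were not run, because they need levels, and no filter and the mean of a gene's probes became the main setting. No paired analysis was possible because each condition had 1 array. Signal over background is unknown here.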

Other observations

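The tests on class II genes, on interferon groups and on a common floor were chosen only after the result was seen, as were the random regroupings and the look at how far the class II genes vary. Of 26 measured genes of T cell activation and costimulation 20 lay within 2-fold between Th17 and Th22, 6 were at least 2-fold lower and 0 higher, with a median of -0.29 log2. Beside Tnfsf8, the growth factor gene Il2 was 8.58-fold lower, Cd40lg 3.29-fold and Tnfrsf9 3.07-fold. Of the genes named in this paragraph, Tnfrsf9, Cd274 and Ccr6 were less than 2-fold apart between Th17 and Th22 after quantile normalization. Against Th0, 9 were lower in Th17 (median -0.49 log2) and 2 in Th22 (median -0.07 log2). Of 13 coinhibitory receptor and ligand genes Btla, Tigit (3.16-fold) and Cd274, which encodes PD-L1 (2.78-fold), were lower in Th17 than in Th22 and Cd101 was higher (median -0.13 log2). Against Th0, 4 were lower and 1 higher in Th17 (median -0.46 log2) and none passed 2-fold in Th22 (median 0). Of 26 chemokine receptor and homing genes 6 were higher in Th17 than in Th22, Gpr15, Ccr8, Cxcr5, Cxcr6, Itgae and Ccr6 (2.06-fold), and Cxcr3 was lower (median 0). S1pr1, which guides exit from lymphoid tissue, was 2.33-fold higher in Th22 and 2.78-fold in Th17 than in Th0, where the list medians were 0.08 and 0.18 log2. Of 35 cytokine genes 5 were higher and 8 lower in Th17 than in Th22 (median -0.25 log2), 4 and 8 in Th22 than in Th0 (-0.12 log2), and 5 and 13 in Th17 than in Th0 (-0.22 log2). The medians of activation and of cytokine genes lay below the 1st percentile of random lists in all 3 comparisons and those of coinhibitory genes in both comparisons of Th17, and those of homing genes above the 99th in both comparisons with Th0.

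Genes of cholesterol synthesis, of the cell cycle, and of glycolysis and hypoxia lay within 2-fold in all 3 comparisons. Of 20 cholesterol synthesis genes 18 were lower in Th17 than in Th22, and the median was -0.34 log2 for Th17 against Th22, -0.33 for Th17 against Th0 and 0.0037 for Th22 against Th0, where the mean (-0.00089 log2) had the opposite sign. For 29 cell cycle genes the medians were -0.07 log2 for Th17 against Th22, -0.18 for Th22 against Th0, where 28 were lower, and -0.25 for Th17 against Th0, where 27 were lower. For 23 genes of glycolysis and hypoxia they were -0.04, 0.07 and 0 in the same order, with 18 higher in Th22 than in Th0. Below the 1st percentile of random lists lay cholesterol synthesis in both comparisons of Th17 and the cell cycle in both comparisons with Th0, and above the 99th lay glycolysis and hypoxia in Th22 against Th0. Of 20 genes of unfolded protein and amino acid stress only the transcription factor gene Atf3 passed 2-fold, and it was lowest in Th17, 4.25-fold below Th22, while Th22 lay 2.59-fold below Th0. That list's medians were 0, -0.18 and -0.12 log2, those against Th0 below the 1st percentile. Of 14 naive T cell genes Igfbp4 (3.39-fold), Txk (3.15-fold) and S1pr1 were higher and Dapl1 lower in Th22 than in Th0 (median 0.04 log2), with the same genes past 2-fold in Th17 against Th0 (median -0.01 log2), and against Th22 only Dapl1 was lower in Th17 (3.17-fold, median -0.03 log2). None of 9 heat shock genes, 4 gamma-delta T cell markers and 7 erythroid and platelet markers passed 2-fold in any comparison.

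Ly6g, Cxcr2 and Il1r2, genes that neutrophils express, were 4.29, 2.27 and 2.47 log2 higher in Th22 than in Th0, and Cxcr2 was named because of its value. In Th17 only Ly6g was that high, 3.87 log2 above Th0. Neutrophils carried over, which the magnetic purification would be meant to remove, are argued against by 23 other neutrophil genes, among them Lcn2, Camp, Ltf and Mmp9: their median difference from Th0 was 0 in both cultures, 16 were equal on all 3 arrays, and the largest difference in either culture was 0.166 log2. With 16 tied the median had to be 0, and levels are unknown, so tied genes may not have been detected. Carried-over cells would still make these genes higher in Th22 and Th17 than in Th0. Tied members showed no such rise, and none of the others differed by more than 0.166 log2. Signal from other Ly6 transcripts is argued against by 15 other Ly6 genes, which differed by at most 0.329 log2 between Th22 and Th0, although 8 of them were equal on all 3 arrays. Expression by the T cells remains a hypothesis, and a difference between single cultures stays open.

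Cd74, 10 of 29 interferon-response genes and Ifng were at least 2-fold lower in Th17 than in Th0. Fewer antigen-presenting cells in the Th17 RNA, cells that the magnetic purification would be meant to remove from every culture, could lower class II genes together, and the median of H2-Aa, H2-Ab1 and H2-Eb1 was -0.20 log2 against -1.98 for Cd74. H2-Ab1 varied by 0.998 log2 over the 3 arrays and differed by only -0.31 log2 between Th17 and Th0, which goes against this explanation for that gene. H2-Aa and H2-Eb1 varied by only 0.12 and 0.20 log2 over the 3 arrays. None of 26 myeloid and dendritic markers passed 2-fold between Th17 and Th0, with 5 lower, 2 higher and 17 equal on all 3 arrays. Had fewer such cells caused the whole fall in Cd74, the 3 genes would be lower by about as much. Their values argue against that. Levels are unknown, but genes not detected in any culture would not speak for such cells in Th0 either. A smaller contribution is not excluded, because the class II list as a whole stood apart towards lower values. Less interferon gamma is another candidate explanation: the median of genes induced mainly by interferon gamma less that of genes induced mainly by type I interferon was -0.97 log2 over all members, as low in 0.75% of 10000 random regroupings of the genes, and -0.58 log2 over the 13 and 13 genes not equal on all arrays, as low in 7.12%. In Th22, Ifng was also lower than in Th0, by 8.36-fold against 13.2-fold in Th17, but only 3 of 29 interferon-response genes were at least 2-fold lower. The median of that list was -0.12 log2 in Th22 and -0.72 log2 in Th17, so it fell far less in Th22 although Ifng fell in both. There the interferon gamma group had a median of -0.55 log2 and the type I group 0, or -0.57 and -0.12 log2 without the tied genes. The interferon results rest on genes that may not have been detected, so less interferon gamma stays open. A smaller part for antigen-presenting cells also stays open.

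Exact ties between arrays were common, and a way of summarising probes may have produced them. A common floor for dim probes would leave the remaining array higher where 2 arrays tie, but it was lower in 51.6% of 7007 such probes, which argues against a floor. Median polish, a robust summary over the probes of a gene, tied all 3 arrays in 78.1% of 2000 simulated unchanged sets of 25 probes and in 43.6% of sets of 11 probes, against 40.3% of the probes measured here. No biological explanation was tested for the ties. If median polish was used, a tie does not show that a gene was equal in the cultures.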
